A study of Lachancea waltii with 8 samples.

How the data were processed

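Lachancea waltii is a budding yeast related to Saccharomyces cerevisiae. The study followed its DNA replication by density transfer, a method that marks old DNA with heavy isotopes so that newly copied DNA can be separated by weight. Per the labels' protocols, wild-type cells grew for 8 generations at 23 °C with heavy carbon and nitrogen. At an OD660 of 0.4 they went into light medium with 100 mM hydroxyurea, a drug that slows replication by limiting nucleotides. After 2 hours the drug was washed out, and timed samples were taken in light medium. DNA cut with PvuII was spun in a caesium chloride gradient, which parted replicated heavy-light DNA from unreplicated heavy-heavy DNA. Each pool was labelled with a different dye, with 1 µg of DNA and 50 units of Klenow fragment per labelling, and both were hybridised to a genomic tiling array.

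The 8 array files fall into 4 samples by their labels, with 9%, 15%, 25% and 45% heavy-light DNA. The titles of the 9% files carry the word arrest, and no other title names a stage. Every sample has 2 files, one in the standard orientation (heavy-light DNA in Cy3) and one with the dyes swapped (heavy-light DNA in Cy5). Both files of a sample hold the same DNA extracts, so they are technical repeats and count as 1 replicate. With 1 culture sample per time point, no test between samples was possible, and no p-value is given. The spread between the dye orientations is the technical error. Each sample sat on a slide of its own (4 slides), so slide and sample cannot be told apart. The collection times are not given in the sources used here.

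The deposited files are Agilent Feature Extraction output, version 9.1.1.1 per the file headers, with 33062 probes of 60 bases on 8 chromosomes, a median of 301 bp apart, and 1227 control spots per array. The deposited processed signals of both channels are intensities that the software had background-subtracted, spatially detrended and dye-normalized with a brightness-dependent curve, per the file headers. The deposited mean, background and background-subtracted signals, also intensity values, served for alternatives. The deposited log ratio of red over green is on the log10 scale per the file headers. The genome build is not given in the sources used here, and positions are those in the probe names. No gene annotation was used here, so genes, centromeres and tRNA genes near the peaks were not analysed here, and places are named by position alone.

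The 2 files labelled 25% hold the same scan. Their mean signals were identical in both channels at 100% of the 34289 spots, and they differed only in the background extraction. In the other samples 0% of the spots were identical. The files of the 25% sample were averaged and counted as 1 array, which leaves 7 separate arrays. Since their labels name opposite dyes, the labels do not settle the direction of that array. The direction of the dye-swap label was taken as likely, because turned the other way 12.8% of the bins would lose replicated DNA between the 15% and the 25% sample by more than 3 times the noise. Values that rest on that direction are given with the sign turned too, or without the array, where the report compares samples with them.

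Control spots and outlier spots (0 to 472 per array) were left out. The log2 ratio of heavy-light over heavy-heavy DNA was taken from the processed signals, turned by the dye labels, centred on each array's median, averaged in 1 kb bins (a median of 3 probes) and averaged over the orientations. It was turned into percent replicated as 100cr/(1+cr), where r is the ratio and the constant c was solved so that the mean over bins equalled the heavy-light percent in the label. The genome-wide mean is therefore set by the label, and only the distribution along the genome is measured. Profiles were smoothed with a Gaussian kernel of SD 3 kb. The technical noise is the SD over bins of the distance between 1 smoothed orientation and the mean of both. For the 25% array it was scaled from the relative noise of the other samples.

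A peak is a local maximum with a prominence (its height above the higher of its flanking valleys) of at least 3 times the technical noise, with a maximum within 4 kb in each orientation, and not within 5 kb of a chromosome end or of a gap over 5 kb. Peaks of different samples within 5 kb were joined. Shared peaks and feature classes were set beside 10000 random rotations of the positions along each chromosome, which describe these arrays and are no test of a condition. The places named are the 10 highest peaks of the 9% sample, the 10 lowest valleys of the 45% sample, and the 5 bins with the largest rise and the 5 with the largest fall in rank from 9% to 45%. They lie at least 20 kb apart and on the same side of the median in both orientations. These rules were fixed before the data were examined. They did not define a valley, which was taken in the script as a local minimum of the smoothed profile, not within 5 kb of a chromosome end or of a gap over 5 kb. Any other place named was chosen after its values were seen, and this is said there.

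The peak caller was tested on simulated data with 90 summits on the real probe positions and unstructured noise of the size seen between orientations. It found 97.8% of the summits within 5 kb in the simulated 9% sample, with 13 of 101 calls away from any summit, and 98.9% in the simulated 45% sample, with 0 such calls. The simulated summits were fewer and further apart than the peaks called in the data, whose median spacing was 30 kb at 9% and 50 kb at 45%. Noise was drawn separately for each orientation, so errors shared by both were absent. These shares describe an easier case and do not give the error of the calls in the data.

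Alternatives were normexp background correction with an offset of 50 (limma 3.58.1 in R 4.3.3), the scanner software's log ratio, loess within arrays, another scaling to percent, a filter on dim and saturated spots, each orientation alone, and other smoothing, prominence, joining and threshold settings. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used. Median signals of the probes ran from 325 to 8334 against backgrounds of 25.5 to 37, and at most 8 probes of an array were not well above background or were saturated. The number of arrays limits the precision.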

Results

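Percent replicated was measured along the 8 chromosomes of Lachancea waltii in 4 samples with 9% (labelled as the arrest, and called the arrest sample here), 15%, 25% and 45% heavy-light DNA. Between 10069 and 10071 bins of 1 kb had values in each sample. The dye orientations correlated across bins with a Pearson r of 0.80 (Spearman rho 0.76) in the 9% sample, 0.87 (rho 0.79) in the 15% sample and 0.98 (rho 0.98) in the 45% sample. Bins are not independent replicates. The 25% sample had 1 array, whose direction is likely but not settled.

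In the 15% sample, the middle 90% of bins lay between 9.82% and 28.0% replicated, around a median of 13.3%. The highest smoothed value was 37.2%. In the 9% sample the range was 5.41% to 14.6%, with a median of 8.47%. In the 45% sample it was 31.2% to 62.1%, with a median of 43.6%, a highest smoothed value of 66.8% and a lowest of 26.9%. The technical noise of the smoothed profiles was 0.459 percentage points in the 9% sample, 0.675 in the 15% sample and 0.586 in the 45% sample. The ranges of the middle 90% are of bins before smoothing, to which this noise does not apply. After smoothing, values ran from 4.45% to 17.4% at 9%, from 8.48% to 37.2% at 15% and from 26.9% to 66.8% at 45%. These differences along the chromosomes were far larger than the noise of the smoothed profiles.

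**Figure D1:**
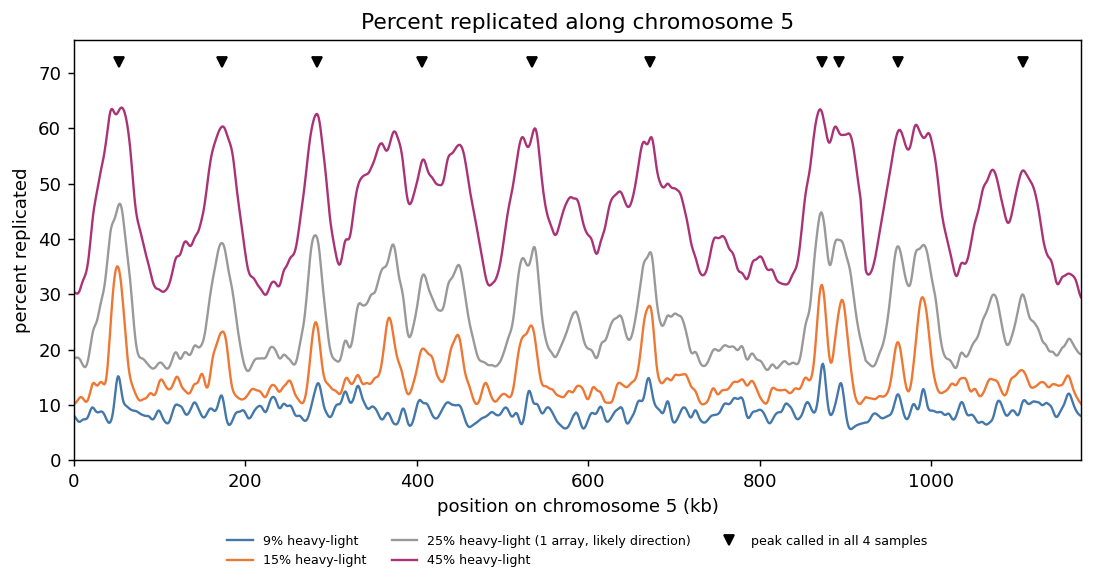
Smoothed percent replicated (vertical axis) against position in kb (horizontal axis) along chromosome 5 in the 4 samples, 1 line per sample, with triangles at the 10 peaks called in all 4 samples. The technical noise is 0.459, 0.675 and 0.586 percentage points in the 9%, 15% and 45% samples, and the 25% line comes from 1 array in its likely direction.

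A core of 63 peaks was called in all 4 samples, with the 25% array in its likely direction. At these sites the median percent replicated was 11.98% (SD over peaks 1.75) in the 9% sample, 25.5% (SD 6.20) in the 15% sample and 59.2% (SD 6.25) in the 45% sample. Each chromosome carried between 5 and 10 of them, the fewest on chromosome 6 and the most on chromosome 5. Neighbouring sites were a median of 138.5 kb apart, with a range from 20.25 kb to 396 kb. Joined over the 9%, 15% and 45% samples alone, 65 peaks were called in all of them. With the 25% array turned, 0 peaks were common to all 4 samples. With peaks joined within 3 kb, 37 were. With a prominence of 10 times the noise, a setting chosen after the data were seen, 28 were.

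The 10 highest peaks of the arrest sample stood between 14.9% and 17.4% replicated, and 9 of the 10 held at least 57.6% in the 45% sample. A peak was called within 5 kb of all 10 at 15% and of 7 at 45%. The highest lay on chromosome 5, in the bin from 873001 to 874000, with 17.4% in the 9% sample, 31.2% in the 15% sample and 62.3% in the 45% sample. Each orientation differed from their mean there by 0.946, 0.891 and 0.142 percentage points. On chromosome 7, the peak in the bin from 887001 to 888000 went from 16.4% to 33.3% and 65.2%, and that from 73001 to 74000 from 15.7% to 33.3% and 64.9%. On chromosome 2, the bin from 587001 to 588000 went from 15.2% to 35.6% and 64.8%. On chromosome 1, the bin from 1016001 to 1017000 went from 15.3% to 34.3% and 64.1%. Further peaks of this kind lay on chromosome 6 at 581001 to 582000 (15.5%), on chromosome 5 at 51001 to 52000 (15.2%) and at 670001 to 671000 (14.9%), and on chromosome 7 at 14001 to 15000 (15.0%). In the 45% sample these 4 sites held 63.1%, 62.9%, 57.6% and 61.3%.

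The exception lay near an end of chromosome 4, in the bin from 8001 to 9000. It was the second highest peak of the arrest sample with 16.5%, rose only to 17.7% in the 15% sample, and held 40.6% in the 45% sample, below that sample's mean of 45%. Each orientation differed from their mean by 0.860, 0.642 and 1.52 percentage points in these samples. Of the 5 core peaks within 30 kb of a chromosome end, a set chosen after the values were seen, 3 stayed below the mean of the 45% sample, and of the 58 elsewhere 3 did, the lowest with 44.2%. Besides this one, the peak at 12.75 kb on chromosome 8 held 14.2%, 16.9% and 39.8% in the 9%, 15% and 45% samples, and the peak at 25.5 kb on chromosome 6 held 11.9%, 14.5% and 40.4%. The peak at 16.25 kb on chromosome 7 went the other way, with 13.8%, 31.3% and 61.7%, and that at 1122.25 kb on chromosome 6 held 12.2%, 24.3% and 54.9%.

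The core peaks, picked for being called in all 4 samples, were wider in the later samples. Measured at 0.5 of the prominence, the 63 core peaks had a median width of 10.1 kb in the 9% sample (interquartile range 9.05 to 12.8 kb), 17.3 kb in the 15% sample (14.7 to 19.4 kb) and 35.5 kb in the 45% sample (22.5 to 55.4 kb). From the 9% to the 15% sample 54 of the 63 became wider. In the likely direction of the 25% array the median was 24.4 kb, 54 were wider than at 15%, and 51 widened further to 45%. With the array turned there are no core peaks to measure. Joined without the 25% sample, the 65 core peaks had median widths of 10.1 kb, 16.8 kb and 32.2 kb at 9%, 15% and 45%. The widest of the 63 measured 117.8 kb at 45%, where peaks were a median of 50 kb apart, so such a width can take in neighbouring peaks. Core widths were not measured at other smoothing or prominence settings. For the 297 peaks of the arrest sample taken as a whole, the result depended on the setting. Their median width was 10.6 kb at 9%, 11.8 kb at 15% and 11.5 kb at 45%, over the 297, 239 and 147 that had a maximum within 5 kb in the sample concerned. At 45% it was 27.3 kb with 5 kb smoothing (17.3 kb at 9%), 21.1 kb at a prominence of 10 times the noise (12.1 kb at 9%), and 4.77 kb with 2 kb smoothing (7.42 kb at 9%).

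**Figure D2:**
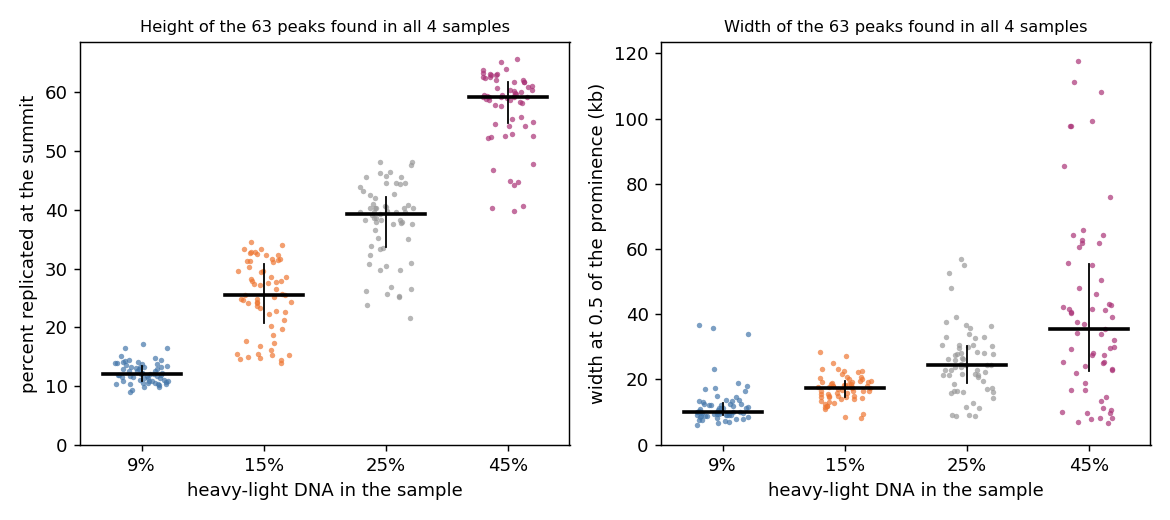
Percent replicated at the summit (left) and width at 0.5 of the prominence in kb (right) of the 63 peaks found in all 4 samples, against the heavy-light percent of the sample. Each point is 1 peak, the thick bar is the median and the thin line spans the interquartile range. The median width went from 10.1 kb at 9% to 35.5 kb at 45%.

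The order of the core peaks by height was close between 15% and 45%, and less so between 9% and 15%. Across the 63 core peaks, the percent replicated at 15% and at 45% correlated with a Pearson r of 0.86 (Spearman rho 0.88). The heights at 9% and 15% were less closely related, with an r of 0.28 (rho 0.31). These are correlations across sites, which are not independent replicates. Over all bins, the 9% profile correlated with the 15% profile at r = 0.39 and with the 45% profile at r = 0.21. The 15% and 45% profiles correlated at r = 0.68. The 25% array correlated with the 15% and 45% profiles at 0.80 and 0.93 in its likely direction, and at -0.80 and -0.93 with the sign turned.

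The samples differed in how many peaks they showed and how many they shared. The numbers of peaks were 297 in the 9% sample, 198 in the 15% sample, 187 in the 45% sample, and 131 on the 25% array (138 turned). The cut on prominence followed each sample's own noise, so these numbers do not rest on 1 common cut. The noise was largest on the 25% array, at 1.41 percentage points, and its peaks needed a maximum in 1 orientation only. Of the 9% peaks, 142 (47.8%) had a 15% peak within 5 kb, against a median of 20.2% and a highest value of 29.6% in the rotations. For 87 (29.3%) a 45% peak lay within 5 kb, against a median of 19.2% and a highest of 26.9%. Of the 15% peaks, 88 (44.4%) had a 45% peak nearby, against a median of 19.2% and a highest of 31.8%. Of the 25% peaks, 114 (87.0%) had a 45% peak within 5 kb in the likely direction and 0 (0%) with the sign turned. A prominence of 10 times the noise left 84, 79 and 124 peaks in the 9%, 15% and 45% samples.

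At the chosen prominence, 69.4% of the sites were counted first in the arrest sample with the 25% array in its likely direction, 53.4% with it turned and 68.6% without it. By this rule every peak of the 9% sample counts as first seen there. The share therefore follows from the number of 9% peaks and shows no order in which sites became active. Joined over samples, there were 428 sites, of which 297 were first seen at 9%, 56 at 15%, 19 at 25% and 56 at 45%. The cut on prominence was highest on the 25% array, whose noise was the largest, and lowest in the 9% sample, whose noise was the smallest. The later numbers also depended on the joining distance. Joined within 10 kb, 37, 8 and 30 were first seen at 15%, 25% and 45%, and joined within 3 kb, 74, 38 and 71. With the 25% array turned, there were 556 sites, with 123 first seen at 25% and 80 at 45%. At a prominence of 10 times the noise, 47.2% of 178 sites were first seen at 9% (84, against 30, 7 and 57 later). Without the standard orientation, 88 were first seen at 15%. With normexp background correction, 30 were first seen at 45%. A peak in 1 sample alone was the case for 220 sites (358 with the array turned), 123 of them in the 9% sample (120 turned). Those 123 held a median of 10.2% at 9%, 13.5% at 15% and 41.1% at 45%, below the mean of the 15% and the 45% samples. The medians over all bins were 8.47%, 13.3% and 43.6%, so at 15% these sites stood close to the typical bin. Of all 297 arrest peaks, 127 lay in bins below the mean of each later sample, both with the 25% array in its likely direction and without it, and 3 with it turned. In the likely direction such bins were 5259 of 10069, a larger share than that of the peaks. The 56 sites with a peak at 45% alone (80 turned) held a median of 16.9% at 15% and 54.9% at 45%. They lay a median of 10.6 kb from the nearest site of an earlier sample, and 27 of them within 10 kb of one. Peaks of the 9% sample alone were a median of 30 kb apart. No rotations were set beside this distance, so it does not show that the sites lay unusually close to earlier ones. From the nearest core peak the 56 sites lay a median of 60.25 kb.

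The advance between samples was uneven along the genome. From 9% to 15%, the middle 90% of bins rose by between 2.27 and 15.8 percentage points, with a largest rise of 25.7. The mean rise is set by the labels. Of the bins, 92.8% rose by more than 3 times the combined noise (2.45 percentage points) and 0% fell by as much. The share was 59.1% at 5 times the noise. The 10% of bins with the highest values at 9% rose by 10.1 percentage points and the 10% with the lowest by 6.03. From 15% to 25%, 93.9% of the bins rose in the likely direction and 75.4% with the sign turned. In the likely direction the share was 56.6% with normexp background correction and 61.3% at 5 times the noise. From 25% to 45% the shares were 100% and 80.9%. Grouped by their value at 15%, the lowest 10% of bins held 10.7% at 15% and 39.2% at 45%, and the highest 10% held 27.3% and 60.4%.

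The 10 lowest valleys of the 45% sample, which are local minima away from chromosome ends and gaps, held between 28.8% and 29.9% replicated. The lowest smoothed value, 26.9%, lay in the last bin of chromosome 1 and so outside this rule. The lowest valley lay on chromosome 2, in the bin from 1268001 to 1269000, with 7.83% at 9%, 11.5% at 15% and 28.8% at 45%, 53.75 kb from the nearest core peak and beyond the last core peak of that chromosome. Each orientation differed from their mean by 0.121, 0.109 and 0.404 percentage points there. Chromosome 2 held 3 more, in the bins from 798001 to 799000 (29.2%), 393001 to 394000 (29.5%) and 952001 to 953000 (29.8%). Chromosome 6 held 2, from 881001 to 882000 (29.0%) and from 325001 to 326000 (29.4%), and chromosome 4 held 2, from 961001 to 962000 (29.0%) and from 559001 to 560000 (29.3%). The others lay on chromosome 1, from 1266001 to 1267000 (29.2%), and on chromosome 5, from 223001 to 224000 (29.9%). The 10 valleys were between 43.5 kb and 128 kb from the nearest core peak. The valleys differed from one another by little more than the noise.

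Some places changed rank between the arrest and the 45% sample by far more than the orientations differed. Of all bins, 19.8% moved by over 50 percentiles from 9% to 45%, against 0.556% between the orientations of the 9% sample and 0% between those of the 45% sample. From 15% to 45% the share was 5.89%. The orientations share the same DNA extracts, so they show only the technical error. Over all bins the 9% and 45% profiles were only weakly related (Spearman rho 0.17), so large changes in rank were common. The places named next are the extremes of this wide reordering. The largest rises were on chromosome 1 at 1136.5 kb, from the 5.34th to the 99.3rd percentile, on chromosome 5 at 41.5 kb (by 91.7 percentiles), 904.5 kb (89.99) and 374.5 kb (88.4), and on chromosome 8 at 623.5 kb (88.0). All 5 stood at or above the 79.7th percentile already at 15%. The largest falls were on chromosome 3 at 1049.5 kb, from the 91.6th to the 2.86th percentile, at 1189.5 kb (fell by 85.9) and 740.5 kb (fell by 84.3), on chromosome 1 at 1259.5 kb (fell by 87.3) and on chromosome 5 at 232.5 kb (fell by 86.9).

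Chromosome ends were among the later parts of the genome at 45%. The bins within 20 kb of an end had a median percentile of 27.1 in the 45% sample (29.0 and 27.3 in the single orientations), below 28.9, the 2.5th percentile of the rotations, and 3 of the 16 ends lay above the genome's median. In the arrest sample their median percentile was 58.8 (63.6 and 56.1), inside the range of 40.5 to 59.3 that holds 95% of the rotations, and 11 of the 16 ends lay above the median. After a regression of the log ratios on the GC content of the probes, added after the data were seen, it was 53.9 at 9%, 57.1 at 15% and 33.4 at 45%. All 3 values lay inside the range that holds 95% of the rotations of the regressed profiles, 40.5 to 59.4 at 9%, 36.9 to 67.0 at 15% and 29.2 to 71.8 at 45%. Without the regression it was 49.6 (55.4 and 46.3) in the 15% sample. On the 25% array it was 40.0 in the likely direction and 60.05 turned.

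Whole chromosomes differed little. At 45%, the means ran from 43.3% on chromosome 2 and 43.7% on chromosome 3 to 46.1% on chromosome 7, and the orientations of a chromosome differed from their mean by at most 0.0651 percentage points. At 9% they ran from 8.82% on chromosome 2 to 9.11% on chromosome 8, with at most 0.0658 between an orientation and the mean. The range of 0.287 percentage points at 9% and 2.75 at 45% was therefore larger than the technical error in both.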

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

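In this part, the regression on GC content was added after the data were seen, and the tests of the 9% maxima against base composition, of the chromosome ends against dye bias and of the ends in the 15% sample were chosen after related results had been seen.

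Chromosome ends stood above the genome's median in both orientations of the arrest sample and below it in both orientations of the 45% sample, with a difference of 31.6 percentiles. The difference was not tested, since each sample is 1 culture. On the arrest side it is weak, because the value of 58.8 lies inside the range of the rotations, and with ends of 10 kb one orientation stood at 45.9. Dye bias is argued against at 20 kb, since it cancels in the mean of both orientations and the lower one stood at 56.1. Base composition is a candidate explanation for the arrest side, since DNA at the ends is poorer in GC (43.5% against 44.7% to 45.0% over chromosomes), and regressing the log ratios on GC content took the 9% value to 53.9. Replication of ends in some cells during the arrest would leave them high in the 15% sample, where the value was 49.6 with the orientations on both sides of 50, and 57.1 after the regression, inside the range of the rotations, so this stays open too. In the 45% sample the ends stood at 33.4 after the regression, which no longer lay below the 2.5th percentile of the rotations of the regressed profile, 29.2.

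Chromosomes 3 and 7 changed sides of the genome's mean in both orientations, and neither difference was tested. Chromosome 3 stood 0.0498 percentage points above the mean at 9% and at -1.34 relative to it at 45%. Chromosome 7 stood at -0.0710 relative to the mean at 9% and 1.06 above it at 45%. At 9% each orientation differed from their mean by 0.0407 on chromosome 3 and 0.0658 on chromosome 7. The sides at 9% therefore rest on margins little larger than the technical error.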

How the results depend on the processing

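The alternatives were listed before the data were examined, except the turned 25% array, signals before dye normalization, a prominence of 10 times the noise, the regression on GC content and the omission of the 25% sample, which were added after. Correlations were compared with their SD over chromosomes. Counts were called moved only when they changed beyond 1.5 times, whatever their spread. Other values were compared with the spread between orientations, pooled over samples. Some counts called unmoved therefore lay outside their spread. The 297 peaks at 9% (spread 24.1) became 249 with normexp and 412 with 2 kb smoothing. At prominences of 2 and 5 times the noise they became 366 and 206. The 63 peaks in all 4 samples (spread 4.24) became 51 with normexp and 87 joined within 10 kb. With the scanner's log ratio, the filter on dim and saturated spots, 2 kb bins, ends of 30 kb, and without the 25% sample no result moved beyond its spread, and counts stayed within 1.5 times. The scanner's log ratio repeated the main values, and the filter concerned at most 8 probes of an array, so neither says much. The 2 kb bins and the ends of 30 kb were run on 4 values each, and the omission of the 25% sample on 2. Where a result moved, the cause was not tested, except that a setting's own threshold or distance sets counts, shares and widths. Median signals lay far above background on every array, and the number of arrays limits the precision. Normexp moved 36 of the 67 values it was run on. That run started from the mean signals and left out dye normalization and spatial detrending, so its moves cannot be assigned to the background alone. Signals before dye normalization moved 15 values. Gene groups, gene ranks and motifs in a genome were not run, for want of annotation here. No paired analysis was possible because the results come from no test.

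Turning the 25% array gave an end percentile of 60.05, a correlation of -0.93 with the 45% profile, 123 sites first seen at 25%, 0 peaks in all 4 samples, 0% of its peaks shared with 45%, rises in 75.4% (from 15%) and 80.9% (to 45%) of bins, a span from the 1st to the 99th percentile of 27.6 percentage points, a range of chromosome means of 1.75 and an early-peak width of 4.32 kb. Normexp gave spans of 18.1, 31.4, 46.2 and 46.3 percentage points at 9%, 15%, 25% and 45%, chromosome ranges of 0.351, 0.972, 2.94 and 3.42, orientation correlations of 0.77 at 9% and 0.90 at 45%, 30 sites first seen at 45%, 76.8% of 25% peaks shared with 45%, rises in 67.7% (9% to 15%) and 56.6% (15% to 25%) of bins, and a width of 10.6 kb at 45%. Signals before dye normalization gave orientation correlations of 0.78 at 9% and 0.95 at 45%, ends at 45.7 at 25%, chromosome ranges of 0.949 at 15% and 2.26 at 25%, rises in 82.8% of bins (15% to 25%), a span of 36.2 at 25%, and widths of 11.1 kb at 25% and 15.2 kb at 45%. Loess gave an orientation correlation of 0.98 and a width of 8.42 kb at 45%, and a chromosome range of 1.83 at 25%. The regression on GC gave 0.98 for the 45% orientations, ends at 53.9, 57.1 and 33.4 at 9%, 15% and 45%, a chromosome range of 2.80 at 45%, 18.9% of bins moving over 50 percentiles, rises in 95.6% (9% to 15%) and 97.4% (15% to 25%) of bins, and widths of 10.5 kb at 15% and 9.64 kb at 45%. The fixed scaling gave a chromosome range of 1.86 at 25% and rises in 89.5% of bins (9% to 15%).

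A prominence of 10 times the noise gave 84, 79, 62 and 124 peaks at 9%, 15%, 25% and 45%, 28 in all 4 samples, 30 first seen at 15% and 7 at 25%, shared shares of 58.3% (9% in 15%) and 64.6% (15% in 45%), and widths of 12.1, 16.5, 21.3 and 21.1 kb. With 5 times, 51.1% of 15% peaks were shared with 45%, and widths were 11.98, 13.4, 15.2 and 13.7 kb. With 2 times, widths were 9.87, 10.4, 9.02 and 10.6 kb. Smoothing with 5 kb gave 179 peaks at 9%, 37 first seen at 45%, and widths of 17.3, 17.3, 22.02 and 27.3 kb. Smoothing with 2 kb gave widths of 7.42, 6.66, 5.59 and 4.77 kb. Joining within 10 kb left 37, 8 and 30 sites first seen at 15%, 25% and 45%, with shared shares of 54.9% (9% in 15%), 59.1% (15% in 45%) and 93.1% (25% in 45%). Joining within 3 kb gave 38 first seen at 25%, 37 in all 4 samples, and shares of 41.8%, 30.3% and 80.9%. Rises above 2 times the noise covered 98.9% (9% to 15%) and 99.5% (15% to 25%) of bins, and above 5 times 59.1% and 61.3%. Ends of 10 kb stood at 53.1 at 9% and 41.4 at 15%. Single probes gave orientation correlations of 0.70, 0.82 and 0.96 at 9%, 15% and 45%.

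Leaving out either orientation (without replicate 1 or 2) gave 275 to 328 peaks at 9%, 41 to 88 sites first seen at 15%, 58 to 64 peaks in all 4 samples, 37.9% to 49.3% of 15% peaks shared with 45%, profile correlations of 0.37 to 0.44 (9% and 15%) and 0.63 to 0.69 (15% and 45%), spans of 13.5 to 17.6 at 9% and 26.4 to 27.4 at 15%, rises in 89.9% to 93.7% of bins (9% to 15%), a chromosome range of 0.271 to 0.327 at 9%, ends at 46.3 to 55.2 at 15%, and widths of 10.4 to 11.4 kb at 15%, 8.80 to 10.5 kb at 25% and 9.24 to 10.5 kb at 45%. Of the values at the named places, 8 of 100 moved among the 9% peaks, 32 of 100 among the 45% valleys (lowest 26.1%, highest 31.3%) and 17 of 100 among the rank changes, with 0 reversals.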

Other observations

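In this part, the test of base composition, which replaced an undecided correlation with GC content of -0.21, the late bins without the 25% array, the comparison of heights with all late bins, and the rule that under 5 consensus matches decide nothing were chosen after related results had been seen.

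Stretches above and below the mean of the 45% sample reached over 100 kb. Those named were chosen after their values were seen. The longest stretch above the mean of the 45% sample covered 186 kb of chromosome 8, from 204 to 390 kb, with a mean of 55.9% replicated at 45% and 18.7% at 15%, and held 4 of the core peaks. The 4 next longest held 1, 1, 1 and 0. They included 1 on chromosome 5 from 326 to 466 kb (140 kb, mean 52.9% at 45%) and 1 on chromosome 2 from 494 to 627 kb (133 kb, mean 57.7%). Of the longest stretches below the mean, 3 reached the ends of chromosomes 3, 7 and 2. They covered 159 kb of chromosome 3 from 1132 kb, 145 kb of chromosome 7 from 970 kb and 140 kb of chromosome 2 from 1235 kb, held means of 36.9%, 37.1% and 35.9% at 45%, and carried 0 core peaks each. A stretch of 140 kb below the mean on chromosome 3, from 66 to 206 kb, held 1.

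The arrest profile also had maxima in DNA that replicated late. A smaller share of its maxima than of all bins lay there, except with the 25% array turned. With the 25% array in its likely direction, bins below the sample mean at 15%, 25% and 45% numbered 5259 of 10069 (5265 without that array, 51 with it turned), and held 127 of the 297 maxima of the 9% sample, standing a median of 1.76 percentage points above the DNA 10 to 20 kb away. Array noise and dye bias are argued against, since the orientations correlated at 0.84 across these bins. A straight-line effect of the probes' GC content alone does not account for the maxima. After regression on it, 124 maxima lay in these bins, and 118 of the 127 still had one within 5 kb. Base composition in a wider sense is not decided by this. The 9% profile correlated with that GC content at only -0.21 across these bins, so the fit could remove little. The composition of whole PvuII fragments was not measured. If origins had fired there during the arrest, the 45% profile was predicted to stand above its flanks, and it stood at -1.65 percentage points. That prediction was too strict, because late bins as a set stood below their flanks, with a median of -2.71, so a few early firings may be hidden, and an effect of the gradient that does not depend on the dye cannot be told apart from them. At the same maxima the 15% profile stood 0.510 percentage points above its flanks (1.03 and 0.146 in the single orientations), against -0.367 for all late bins. The technical noise of 0.675 is that of single bins and gives no error for a median over 127 maxima. At 15%, 68.5% of the maxima stood above their flanks, and at 45% 31.5% did. Across late bins the 9% profile correlated with the 15% profile at 0.52 and with the 45% profile at 0.04. The 15% profile had been predicted to stand above its flanks too, and it did, while the 45% profile did not. Firing during the arrest therefore stays open.

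In the 45% sample, the 1st and 99th percentiles of bins stood at 28.7% and 65.5% replicated, the widest span of the 4 samples but short of fully unreplicated or replicated DNA. Brightness-dependent dye normalization is argued against as what keeps the span this small, since the span widened by only 2.10% on signals before that step. Normexp widened it from 36.8 to 46.3 percentage points. Mixing of the pools in the gradient and cells out of step with one another were not tested, and no biological explanation was tested.

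A hypothesis that summits lie in AT-rich DNA was tested on probe sequences within 1 kb of the 63 core peaks. Their AT content was 55.7%, against a median of 55.2% in the rotations, and 98% of the rotations were lower. The difference is small. Within 2 kb, 99.8% of the rotations were lower. Around the 187 peaks of the 45% sample, whose profile rose with GC content over all bins (r = 0.13), AT content was 55.9% and 100% of the 10000 rotations were lower. The 9% profile fell with GC content over all bins (r = -0.14), and every core peak needed a peak at 9%. A 2nd hypothesis, that the origin consensus of Saccharomyces cerevisiae is denser there, could not be decided from probes alone. They held 1 match within 1 kb, and 72.2% of the rotations had fewer per kb. Within 2 kb they held 3 matches, or 0.0531 per kb, and 98% of the rotations had fewer.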
